A study of Mus musculus with 16 samples.

How the data were processed

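Gene expression was measured by RNA-seq of polyadenylated RNA in 16 libraries of MPI-2 cells, 4 for each combination of exposure to Mycobacterium abscessus or none and day 1 or day 5. RNA had been extracted with Maxwell RSC instruments. Per the submitters' processing notes, reads were aligned and counted with STAR on GRCm39, with no version of the program or release of the annotation given. The deposited files hold raw counts per gene for each library, of the reverse-strand kind per the file names, for 55359 genes with versioned Ensembl identifiers, and whole numbers with a different total in each file were found on checking. Totals per library lay between 46154875 and 81995629, so that 3 counts over a group of 4 libraries, the floor used where a group had 0 counts, correspond to 0.0104 CPM in uninfected day 5 libraries. CPM are counts scaled to the library totals after normalisation.

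Symbols came from GENCODE M21, matched on the identifier without its version, for 52083 of the 55359 genes, and the others held 0.45% of counts. That release rests on an older mouse assembly than the one the submitters used, so no coordinates are given. How reads shared by close paralogs, such as the Oas1, Ifit3, Apol9, Bcl2a1 and class I H2 genes, were assigned is not stated, and counts of single members of such families carry that limit.

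Groups followed the labels. Genes passed edgeR's filterByExpr by group (17190 genes), libraries were scaled by TMM, and 1 quasi-likelihood model with robust dispersion (edgeR 4.0.16, R 4.3.3) was fitted to all 16 libraries with a mean per group. The common biological coefficient of variation was 0.149. Exposed and uninfected cells were compared at day 1 and at day 5, the change of that effect between days was tested as an interaction, and uninfected cells were compared between days. Tests were two-sided, adjusted by Benjamini-Hochberg over the genes tested, and called at an adjusted p under 0.05. Replicate numbers were not used as a block. Principal components were computed on log2 CPM with a prior count of 2.

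For 35 gene lists fixed in advance, covering senescence, the cell cycle, inflammation, interferon, defence, metabolism, macrophage identity and markers of other cell types, called members were counted over all genes tested and adjusted over the list alone. Lists with at least 5 tested members (31) were tested with camera (limma 3.58.1) at the preset correlation of 0.01, adjusted over lists within a comparison, then with an estimated correlation and with fry. Members were chosen from general knowledge of each process, and lists share genes.

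Genes named in the text followed a rule. For each exposure comparison and for the interaction it takes the 10 higher and 10 lower called genes with the largest log2 fold change, a mean of at least 5 CPM in the higher group, a symbol that is not a predicted or clone name and, outside the interaction, libraries that do not overlap between groups. The comparison of uninfected days takes 5 in each direction. From every list up to 4 members with the smallest p are added, and 22 genes of senescence and inflammation are always included. A gene that the rule takes for 1 comparison could be given for the others. Outside the rule, and chosen after their values were seen, Ccl20, Serpinb2 and Tlr4 are named for their 0 counts, and Sgsh and Pycard for their few counts.

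The comparisons, tests, lists, rule and most alternatives were set before the data were examined. Alternatives were DESeq2 1.42.0, RLE size factors, no filter beyond 1 read, a filter of 1 CPM in 4 libraries, fits on the libraries of a comparison alone, the replicate number as a block, each library left out, exposed day 5 without the 2 libraries of another code series, and replicates 1 and 2 or 3 and 4 alone. List members under each alternative, and lists and overlaps with each library left out, were added after seeing the data. Figures were drawn with matplotlib 3.10.9.

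The tests were run on simulated data with 16812 genes, of which 16612 (16412 for the interaction) were unchanged. At a log2 change of 0.5, 1 and 2, edgeR called 44.8%, 88.1% and 98.5% of changed genes at day 1, 50.7%, 90.9% and 100% at day 5, 22.4%, 75.2% and 97% for the interaction and 56.1%, 79.1% and 100% for uninfected days. Unchanged genes called numbered 7, 10, 9 and 4. Camera called the 1 raised list of 30 genes and 0 of 20 unchanged lists. Genes were drawn independently, with 1 dispersion per gene for all groups, and changed genes came from the more abundant ones. The simulation thus does not cover groups of unequal spread or lists whose members move together. In the real data the estimated correlation was 0.85 for the G1/S list and 0.917 for the G2/M list. It was estimated over all 16 libraries and is the same in every comparison. Exposed day 5 libraries, with the widest spread, thus weigh on it also in comparisons that leave them out.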

Results

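The series holds 16 RNA-seq libraries of MPI-2 cells, a mouse line of alveolar-like macrophages grown in GM-CSF, the cytokine on which alveolar macrophages depend. Wild-type cells had been exposed to Mycobacterium abscessus, a nontuberculous mycobacterium that can persist inside macrophages, or left uninfected, and were profiled at day 1 and at day 5. Each of the 4 groups had 4 replicates, labelled as biological and all of a single cell line. The title of the series sets the experiment in a study of cell senescence during chronic intracellular infection. Strain, dose and the share of cells that held bacteria were not given in the sources used here, so every value is an average over exposed cultures. Total counts per library lay between 46154875 (exposed day 1, replicate 4) and 81995629 (exposed day 1, replicate 1), and 17190 genes were tested.

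The first principal component, with 61.5% of the variance, placed the 4 exposed day 5 libraries between 90.1 and 127.6, the exposed day 1 libraries between -10.7 and 0.7, and the 8 uninfected libraries between -58.4 and -43.8. Exposed day 5 libraries differed most among themselves, with a median standard deviation per gene of 0.299 log2 CPM, against 0.113 to 0.148 in the other groups. Exposed day 1 replicate 4 scored 34.2 on the third component, against 5 to 8 for the other libraries of its group. Mitochondrially encoded transcripts took 0.904% ± 0.195 of counts in exposed day 5 libraries and 1.58% ± 0.119 in uninfected day 5 libraries (SD, n = 4 each). Errors on CPM are standard deviations over 4 libraries, errors on log2 fold changes are standard errors, and intervals from low counts cover counting error only. The standard errors rest on 1 dispersion per gene shared by the 4 groups, so they do not measure the spread of a single group.

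**Figure D1:**
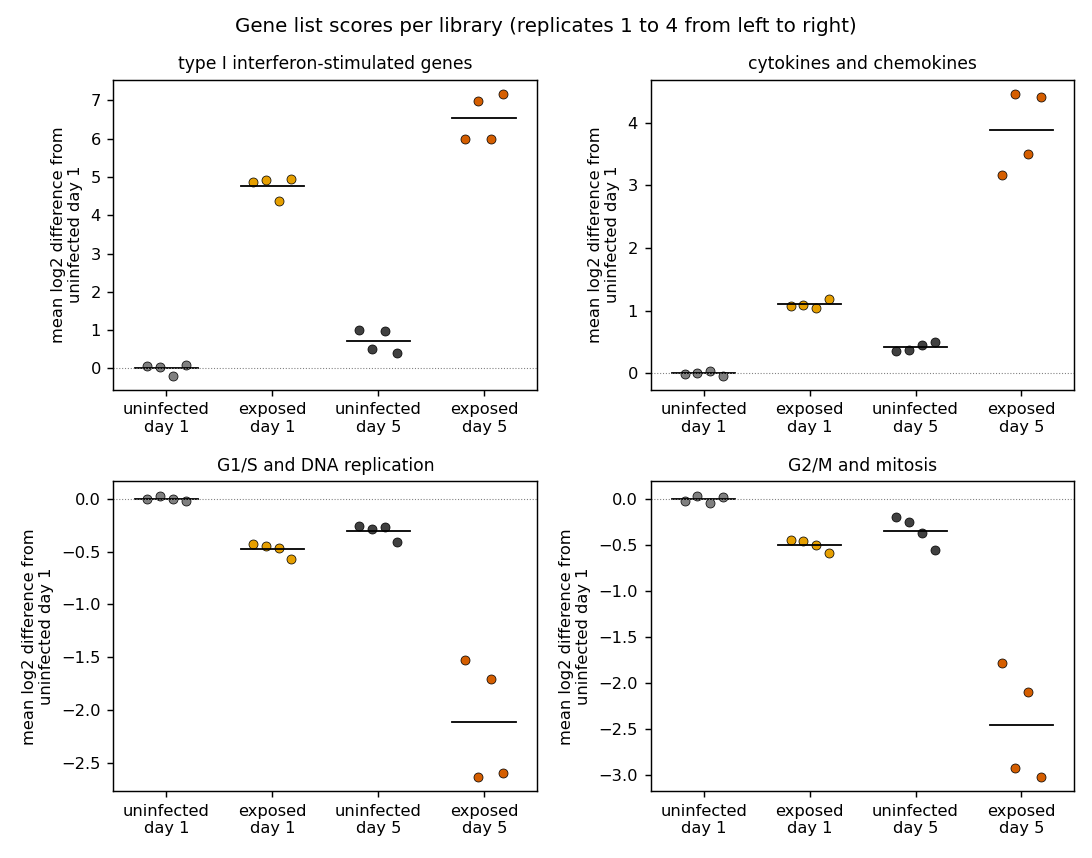
Mean log2 difference of 4 gene lists from the uninfected day 1 mean, for each of the 16 libraries (points) and each group (bars at the mean). The exposed day 5 libraries lie between 5.99 and 7.17 for type I interferon-stimulated genes and between -3.02 and -1.78 for G2/M genes.

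The day 1 comparison asks which transcripts changed early in exposure. Type I interferon-stimulated genes, an antiviral set switched on by interferon receptors, rose as a group: all 32 tested members were higher in exposed cells, with a median log2 fold change of 5.41. Rtp4 (ENSMUSG00000033355.7), a member of the set, went from 0.316 ± 0.0421 to 74.1 ± 10.4 CPM (log2 fold change 7.84 ± 0.28, n = 4 against 4, adjusted p = 8.85e-12). Oasl2 (ENSMUSG00000029561.18) rose by 7.67 ± 0.34 on the log2 scale, Usp18 (ENSMUSG00000030107.11), which removes ISG15 from proteins, by 7.53 ± 0.48, and Rsad2 (ENSMUSG00000020641.17), the antiviral enzyme viperin, by 6.78 ± 0.59. Isg15 (ENSMUSG00000035692.8), a ubiquitin-like modifier, rose from 2.00 ± 0.0571 to 68.2 ± 15.1 CPM (adjusted p = 6.68e-09).

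Adjusted over the list alone, 32 of the 32 interferon-stimulated genes were higher, and camera placed the list above other genes (adjusted p = 8.6e-56 with the preset correlation, adjusted p = 0.057 with an estimated correlation). Camera values below use the preset correlation, and none of those calls held with an estimated correlation. That correlation was estimated over all 16 libraries, exposed day 5 among them. It is therefore not a value of the day 1 or the uninfected libraries alone. Genes typical of interferon-gamma responses followed: 19 of 22 were higher and 1 lower, with the same counts adjusted over the list alone (camera adjusted p = 1.52e-18, adjusted p = 0.115 with an estimated correlation). Gbp3, a guanylate-binding protein of cell-autonomous defence, rose by 4.01 ± 0.31 on the log2 scale, and Socs1, a feedback inhibitor of cytokine receptors, by 1.74 ± 0.15. Their median log2 fold change was 2.28, or 2.00 with Nos2, absent from all 4 control libraries, set at its lower bound.

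Several inflammatory genes also rose at day 1. Il1b (ENSMUSG00000027398.14), the pyrogenic cytokine interleukin-1 beta, went from 5.71 ± 0.548 to 34.8 ± 4.58 CPM (log2 fold change 2.60 ± 0.27, adjusted p = 3.29e-06). Tnf (ENSMUSG00000024401.15), tumour necrosis factor, went from 15.0 ± 1.02 to 58.0 ± 13.2 CPM (adjusted p = 0.000209), and the chemokine Cxcl10 (ENSMUSG00000034855.14) rose by 4.33 ± 0.52 on the log2 scale. Of 28 cytokines and chemokines, 12 were higher and 1 lower, and 13 and 1 when adjusted over the list alone (camera adjusted p = 3.01e-07, adjusted p = 0.208 with an estimated correlation). Of 29 NF-kB response genes 22 were higher and 0 lower, and 23 and 0 when adjusted over the list alone (camera adjusted p = 2.18e-19, adjusted p = 0.121 with an estimated correlation). They were led by Tnip3, an inhibitor of NF-kB signalling (3.98 ± 0.18), and Nfkbie, an inhibitor of the kappa-B family (2.25 ± 0.12). Antimicrobial effectors had 13 of 20 higher and 1 lower, and 14 and 1 when adjusted over the list alone (camera adjusted p = 9.18e-08, adjusted p = 0.115 with an estimated correlation). Acod1 (ENSMUSG00000022126.7), the enzyme that makes itaconate, rose from 3.82 ± 0.814 to 61.7 ± 1.97 CPM, and Hp, haptoglobin, rose by 2.55 ± 0.15 on the log2 scale.

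Proliferation genes called at day 1 were all lower, and many were not called. Of 33 genes of G1/S and DNA replication 15 were lower and 0 higher, and 19 and 0 when adjusted over the list alone, with a median log2 fold change of -0.50 (camera adjusted p = 1.23e-08, adjusted p = 0.562 with an estimated correlation). Of 32 genes of G2/M and mitosis 13 were lower and 0 higher, and 24 and 0 when adjusted over the list alone (median -0.51, camera adjusted p = 7.15e-08, adjusted p = 0.562 with an estimated correlation). Neither list was called by fry (adjusted p = 0.059 for G1/S and 0.0904 for G2/M). Both the estimated correlation and fry draw on the spread within all 16 libraries, exposed day 5 included. Of 29 DNA damage response genes 17 were lower and 0 higher, and 21 and 0 when adjusted over the list alone (camera adjusted p = 4.85e-10, adjusted p = 0.227 with an estimated correlation), among them Atm, the kinase that signals double-strand breaks (-0.53 ± 0.10). The clock repressor Nr1d1 (ENSMUSG00000020889.12) fell the most among the genes named by rank, from 29.3 ± 1.49 to 9.98 ± 0.419 CPM (log2 fold change -1.55 ± 0.10, adjusted p = 9.19e-10). Of 18 antigen-presentation genes 8 were higher and 4 lower at day 1 on both adjustments (camera adjusted p = 0.0413, adjusted p = 0.589 with an estimated correlation). The adjusted p was 0.0559 with the replicate block, 0.0556 without exposed day 1 replicate 1 and 0.0521 without uninfected day 1 replicate 1. H2-Eb1 shifted by -1.29 ± 0.24 and H2-Aa by -1.21 ± 0.27, while Ciita rose by 1.36 ± 0.16 and H2-K1 by 1.09 ± 0.13.

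Across all tested genes, edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment called 2297 genes higher and 1800 lower at day 1, of which 765 and 99 changed at least 2-fold. A fit on the 8 day 1 libraries by themselves called 3650 higher and 3371 lower, and fits on replicates 1 and 2 or on replicates 3 and 4 called 813 and 568 higher. Leaving out exposed day 1 replicate 4, which lay apart, gave 1706 higher and 1220 lower, and leaving out uninfected day 1 replicate 4 gave 1706 and 1236.

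At day 5 the inflammatory genes stood far higher. Il1b reached 1696 ± 789 CPM in exposed cells against 8.86 ± 0.983 in uninfected day 5 cells (log2 fold change 7.58 ± 0.33, n = 4 against 4, adjusted p = 1.01e-11). Tnf reached 688 ± 377 against 16.3 ± 0.592 CPM (5.40 ± 0.34, adjusted p = 1.03e-09). Il6 (ENSMUSG00000025746.12), the acute-phase cytokine interleukin-6, rose by 7.36 ± 0.56 on the log2 scale. The monocyte chemoattractant Ccl2 (ENSMUSG00000035385.6) rose by 3.47 ± 0.51, and Ccl17, a T-cell chemokine, by 4.89 ± 0.32. Csf2 (ENSMUSG00000018916.6), which encodes GM-CSF itself, had 0 counts in all 4 uninfected day 5 libraries and 1656 counts in the exposed ones, at least 622-fold higher with a floor of 3 counts over the group. Of 28 cytokines and chemokines 23 were higher and 2 lower, and 24 and 2 when adjusted over the list alone, with a median log2 fold change of 4.09, also with Csf2 at its bound (camera adjusted p = 1.95e-10, adjusted p = 0.137 with an estimated correlation). Of 29 NF-kB response genes 27 were higher and 0 lower, on both adjustments (camera adjusted p = 5.77e-17, adjusted p = 0.137 with an estimated correlation), with Tnip3 at 7.53 ± 0.20 and Tnfaip3, the ubiquitin editor A20, at 3.86 ± 0.17.

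Antimicrobial effectors were higher too. Hp (ENSMUSG00000031722.11) went from 5.37 ± 0.679 to 744 ± 133 CPM (log2 fold change 7.12 ± 0.18, adjusted p = 7.27e-16), Saa3 (ENSMUSG00000040026.9), a serum amyloid A protein, from 0.723 ± 0.163 to 117 ± 31.4 CPM, and Acod1 from 5.25 ± 1.01 to 602 ± 309 CPM. Nos2 (ENSMUSG00000020826.10), inducible nitric oxide synthase, rose by 6.22 ± 0.86 on the log2 scale but stayed at 22.4 ± 23.0 CPM, with a standard deviation as large as its mean. Of 20 antimicrobial effectors 17 were higher and 0 lower, and 18 and 0 when adjusted over the list alone (camera adjusted p = 9.13e-11, adjusted p = 0.111 with an estimated correlation). All 32 interferon-stimulated genes were higher on both adjustments, with a median of 6.43 (camera adjusted p = 5.13e-26, adjusted p = 0.137 with an estimated correlation), and Rsad2 reached 1181 ± 921 CPM. Of 22 genes of the interferon-gamma type 19 were higher and 2 lower on both adjustments (camera adjusted p = 9.6e-09, adjusted p = 0.248 with an estimated correlation). Antigen-presentation genes had 12 of 18 higher and 3 lower on both adjustments (camera adjusted p = 0.000292, adjusted p = 0.248 with an estimated correlation), with B2m, the light chain of class I molecules, at 2.01 ± 0.14.

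Secreted proteases and their inhibitors were mostly higher at day 5. Of 17 genes of metalloproteinases and the plasminogen system 16 were higher and 1 lower on both adjustments, with a median of 1.82, also with Serpinb2 at its bound (camera adjusted p = 3.06e-06, adjusted p = 0.154 with an estimated correlation). Mmp12 (ENSMUSG00000049723.15), macrophage elastase, rose by 1.97 ± 0.24 and the gelatinase Mmp2 by 5.04 ± 0.20 on the log2 scale. The exception was Mmp8 (ENSMUSG00000005800.4), a collagenase, which fell from 24.3 ± 4.47 to 0.989 ± 0.138 CPM (log2 fold change -4.62 ± 0.17, adjusted p = 1.28e-13). The rise ranked first by fitted value was that of H2-M2 (ENSMUSG00000016283.14), a nonclassical class I gene, from 0.0422 ± 0.0315 to 219 ± 96.8 CPM (12.30 ± 0.45), and reads it may share with other class I genes were not resolved. Genes with 0 or few counts in uninfected cells, such as Csf2, have folds known only as bounds or wide intervals, so their true rank is open.

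Every proliferation gene on the fixed lists was lower at day 5. All 33 genes of G1/S and DNA replication (median log2 fold change -1.82, camera adjusted p = 3.79e-15, adjusted p = 0.248 with an estimated correlation) and all 32 genes of G2/M and mitosis (median -2.06, camera adjusted p = 3.15e-16, adjusted p = 0.248 with an estimated correlation) were lower on both adjustments. Fen1, the flap endonuclease of lagging-strand synthesis, fell by 2.06 ± 0.13 on the log2 scale, and Aurka, a spindle kinase, by 1.99 ± 0.17. Mki67 (ENSMUSG00000031004.9), the proliferation marker Ki-67, fell from 411 ± 82.5 to 180 ± 52.9 CPM (log2 fold change -1.19 ± 0.17, adjusted p = 6.79e-06). Of 29 DNA damage response genes 26 were lower and 2 higher on both adjustments (camera adjusted p = 2.31e-09, adjusted p = 0.248 with an estimated correlation). The share of counts from mitochondrially encoded genes was lower in the same libraries.

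Many energy and lipid genes were also lower at day 5. Of 32 nuclear genes of oxidative phosphorylation 24 were lower and 0 higher, and 25 and 0 when adjusted over the list alone, with a median of -0.44 (camera adjusted p = 3.06e-06, adjusted p = 0.335 with an estimated correlation). Of 13 mitochondrially encoded genes 10 were lower and 0 higher on both adjustments (camera adjusted p = 0.00605, adjusted p = 0.44 with an estimated correlation). Of 24 genes of LXR and lipid handling 16 were lower and 3 higher on both adjustments (camera adjusted p = 0.000563, adjusted p = 0.248 with an estimated correlation). Srebf1, the lipogenic transcription factor SREBP-1, fell by 1.87 ± 0.15, while Abca1, a cholesterol exporter, rose by 1.62 ± 0.11. Of 33 lysosomal genes 19 were higher and 4 lower, and 19 and 5 when adjusted over the list alone (camera adjusted p = 0.0185, adjusted p = 0.673 with an estimated correlation, or 0.0801 without exposed day 5 replicate 2), with the protease Ctsb at 1.53 ± 0.15. Ribosomal protein genes had 14 of 30 lower and 1 higher on both adjustments (camera adjusted p = 0.00938, adjusted p = 0.553 with an estimated correlation).

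edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment called 4918 genes higher and 4879 lower at day 5, of which 2343 and 1604 changed at least 2-fold. None of the alternatives run for these counts (another test, scaling, filter, replicate subset or block, or a library left out) moved either by over 1.5 times. Among the called genes named in the text, Ciita, H2-Aa and H2-Eb1 had exposed and uninfected libraries that overlapped at day 5.

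Over the 31 gene lists tested, camera with the preset correlation called 13 up and 3 down at day 1 and 11 up and 7 down at day 5. With an estimated correlation camera called 0 lists at either day (lowest adjusted p = 0.057 and 0.111), with 7 and 6 up and 0 down at an unadjusted p under 0.05, and the self-contained test fry called 13 up and 1 down and 15 up and 12 down. In fits of the 8 libraries of a day, 14 and 18 lists were called with the real labels. Other splits of the same libraries, some of which keep most libraries of 1 label together, reached 17 and 19.

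**Figure D2:**
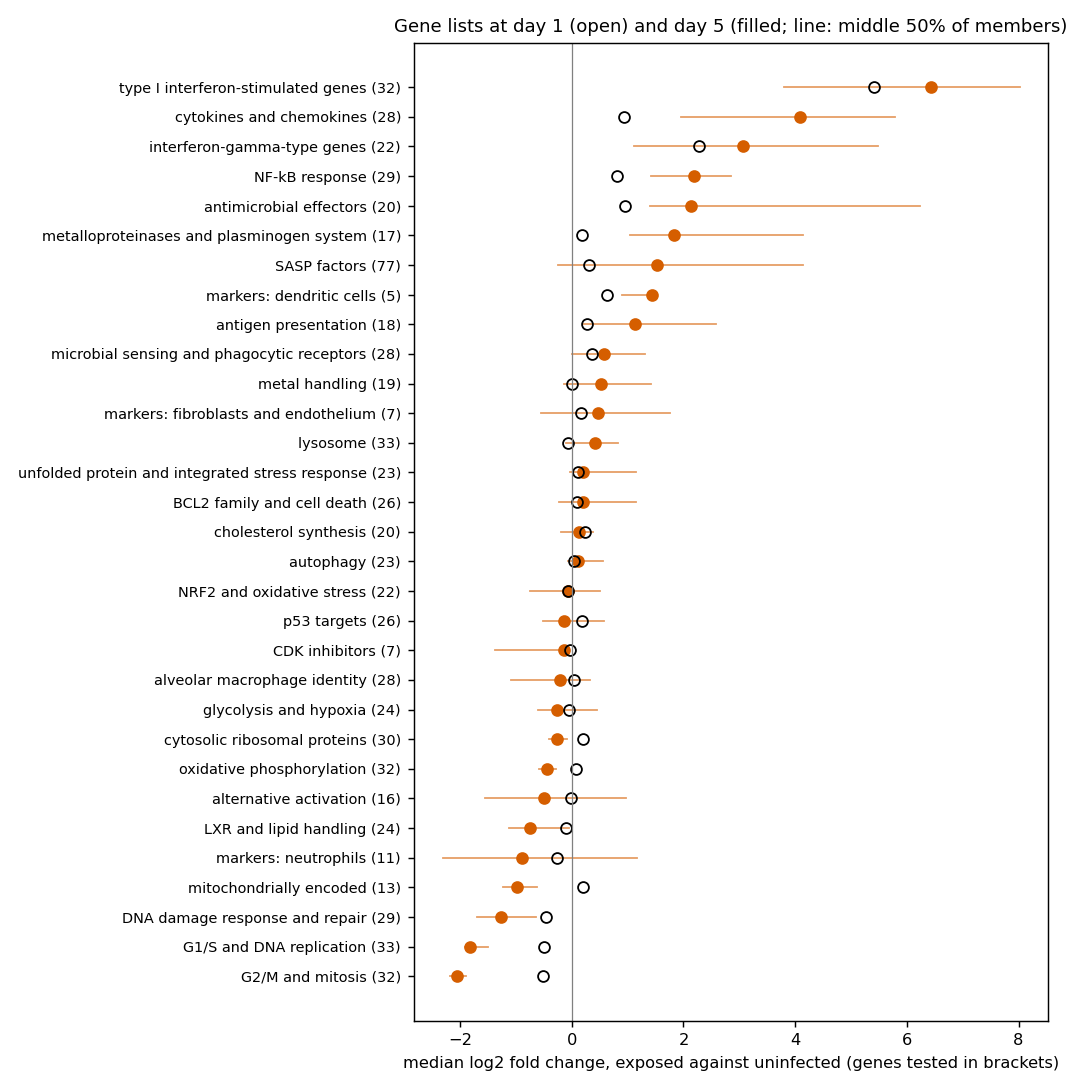
Median log2 fold change of each gene list tested by camera, exposed against uninfected, at day 1 (open circles) and at day 5 (filled circles); lines span the middle 50% of members at day 5. Interferon-stimulated genes lie at 5.41 and 6.43, and the G2/M genes at -0.51 and -2.06.

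Genes tied to senescence did not move together. Cdkn1a (ENSMUSG00000023067.15), the p53-induced cell cycle inhibitor p21, stood at 274 ± 89.5 CPM in exposed and 300 ± 15.1 CPM in uninfected day 5 cells. It was not called at either day (log2 fold change -0.09 ± 0.15 and -0.13 ± 0.15, adjusted p = 0.705 and 0.484), though without exposed day 5 replicate 2 it was called lower (-0.31, adjusted p = 0.048). The exposed day 5 libraries differed among themselves, with Cdkn1a at 371 and 327 CPM in replicates 2 and 4 and at 211 and 186 CPM in replicates 1 and 3, against 277 to 310.4 CPM in uninfected day 5 libraries. Cdkn2a (ENSMUSG00000044303.7), whose count pools the transcripts for p16 and p19ARF, was not called at day 1 (0.22 ± 0.14) and fell at day 5 from 11.9 ± 1.55 to 3.45 ± 0.715 CPM (-1.78 ± 0.14, adjusted p = 4.34e-09). Cdkn2b (ENSMUSG00000073802.6), which encodes p15, was not called at either day (0.32 ± 0.17 and -0.09 ± 0.16), though it was called higher at day 1 in the fit on the day 1 libraries alone (0.33, adjusted p = 0.0156). Of the 7 CDK inhibitors 0 were higher and 1 lower at day 1, and 1 higher and 3 lower at day 5, on both adjustments, with no camera call (adjusted p = 0.63 and 0.061, the latter 0.0378 without exposed day 5 replicate 2 and 0.0479 without replicate 4). The test fry called the list down at day 5 (adjusted p = 3.66e-07) and not at day 1 (adjusted p = 0.575). Cdkn2c was lower on both days (-0.77 ± 0.16 and -2.18 ± 0.16), Cdkn2d at day 5 (-0.98 ± 0.11), and the higher one was Cdkn1c (0.98 ± 0.28), at a mean of 0.889 CPM in exposed cells. In the fit on the day 1 libraries alone Cdkn2d was called lower at day 1 as well (-0.215, adjusted p = 0.0138).

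Lmnb1 (ENSMUSG00000024590.9), the nuclear lamina protein whose loss is a common mark of senescent cells, fell from 95.4 ± 13.5 to 17.4 ± 6.81 CPM at day 5 (log2 fold change -2.45 ± 0.19, adjusted p = 9.67e-09), after a change of -0.68 ± 0.18 at day 1. Hmgb1 (ENSMUSG00000066551.13), a chromatin protein that senescent cells release, fell by 1.04 ± 0.09 on the log2 scale at day 5. Glb1 (ENSMUSG00000045594.11), which encodes the lysosomal beta-galactosidase behind the usual senescence stain, was not called at day 1 (0.02 ± 0.12) and rose at day 5 by 0.63 ± 0.12 (adjusted p = 0.000132). Gdf15 (ENSMUSG00000038508.8), a stress-induced secreted factor, was not called at either day (-0.20 ± 0.12 and -0.19 ± 0.12). It was called lower at day 1 in the fit on the day 1 libraries alone (-0.19, adjusted p = 0.0147) and at day 5 without exposed day 5 replicate 2 (-0.29, adjusted p = 0.041). Trp53 (ENSMUSG00000059552.14), which encodes p53, rose by 0.25 ± 0.07 at each day. Its day 1 call was lost with no filter (0.22, adjusted p = 0.129), in replicates 1 and 2 (0.24, 0.109) and in replicates 3 and 4 (0.25, 0.249), and its day 5 call in replicates 1 and 2 (0.13, 0.213). Bcl2 (ENSMUSG00000057329.8), an inhibitor of apoptosis, was not called at day 1 (-0.01 ± 0.09) and rose by 0.62 ± 0.09 at day 5, when Bcl2l1 (ENSMUSG00000007659.19), which encodes BCL-XL, fell by 0.49 ± 0.11.

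Of 77 tested factors of the senescence-associated secretory phenotype, 21 were higher and 6 lower at day 1, and 22 and 8 when adjusted over the list alone (camera adjusted p = 0.00938, adjusted p = 0.562 with an estimated correlation). At day 5, 45 were higher and 19 lower, and 45 and 20 when adjusted over the list alone, with a median of 1.53, also with Ccl20 and Csf2 at their bounds (camera adjusted p = 0.000161, adjusted p = 0.254 with an estimated correlation). The list shares Il1b, Il6, Tnf, Ccl2 and other cytokines with the inflammatory list. Of 26 p53 targets 7 were higher and 0 lower at day 1 on both adjustments (camera adjusted p = 0.0256, adjusted p = 0.198 with an estimated correlation), led by the death receptor Fas (1.69 ± 0.13). At day 5, 8 were higher and 9 lower, and 8 and 11 when adjusted over the list alone, with no camera call (adjusted p = 0.637) and a median (-0.14) and mean (0.14) of opposite sign. Among all genes tested, 57% were called at day 5, with 50.2% of those calls higher.

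**Figure D3:**
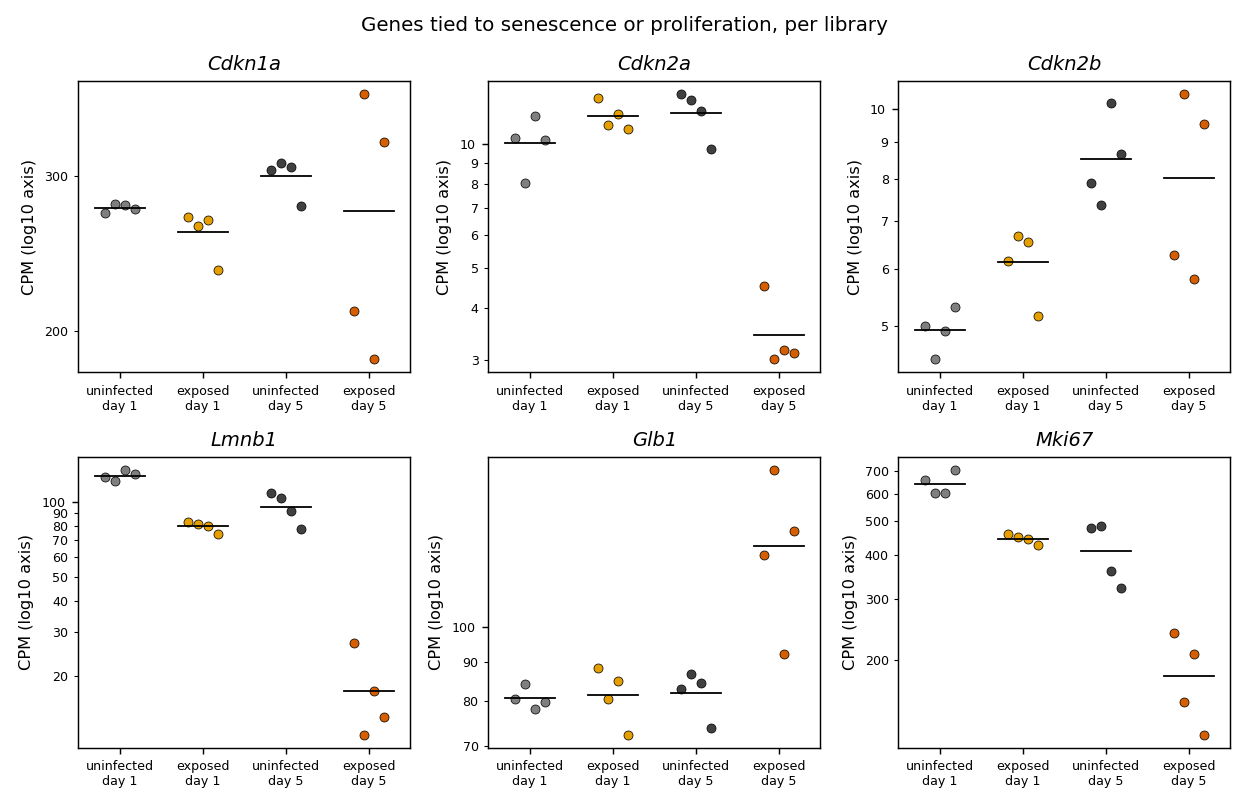
CPM per library, on a log10 axis, of 6 genes tied to senescence or proliferation (points, 4 per group; bars at the group mean). Cdkn1a lies between group means of 259 and 300 CPM, and Lmnb1 falls to a mean of 17.4 CPM in exposed day 5 libraries.

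The change of the exposure effect between the days was tested directly. The exposure effect on Il1b shifted up by 4.98 ± 0.38 on the log2 scale (n = 4 per group, adjusted p = 9.27e-08), that on Saa3 by 5.94 ± 0.37 and that on Lcn2, an iron-withholding lipocalin, by 6.19 ± 0.38. The effect on Lmnb1 shifted by -1.78 ± 0.26 and that on Cdkn2a by -2.00 ± 0.20, while Cdkn1a showed no called change (-0.04 ± 0.22, adjusted p = 0.913). The effect on Mmp8 shifted by -4.21 ± 0.21.

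Of interferon-stimulated genes, 11 of 32 effects were larger at day 5, 2 smaller and 19 not called, and 12 and 2 when adjusted over the list alone (camera adjusted p = 0.000443, adjusted p = 0.534 with an estimated correlation, but 0.0733 by fry). Rtp4 and Oas2, an RNA-sensing synthetase, were among the smaller, at -1.03 ± 0.36 and -1.45 ± 0.26. Uninfected levels rose between the days, for Rtp4 from 0.316 to 1.36 CPM and for Oas2 from 1.60 to 6.54 CPM. The smaller effects therefore do not mean lower levels in exposed cells. The call on Rtp4 ended with no filter (adjusted p = 0.132), with the replicate block (0.0516), without the libraries of the other code series (0.0816) and without single libraries such as exposed day 5 replicate 3 (0.0649). Of 28 cytokines 17 effects shifted up and 3 down, and 18 and 3 when adjusted over the list alone (camera adjusted p = 3.66e-08, adjusted p = 0.32 with an estimated correlation). Of 32 G2/M genes all shifted down on both adjustments (camera adjusted p = 1.28e-14, adjusted p = 0.345 with an estimated correlation), as did 31 of 33 G1/S genes (camera adjusted p = 1.51e-12, adjusted p = 0.352 with an estimated correlation). Of 77 secretory-phenotype factors 34 shifted up and 17 down, and 36 and 17 when adjusted over the list alone (camera adjusted p = 0.000101, adjusted p = 0.345 with an estimated correlation).

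In all, edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment called the change in 6173 genes, 2826 up and 3347 down. The larger direction turned with scaling: RLE size factors gave 3062 up and 2992 down, and DESeq2 3356 and 3245. Fits on replicates 1 and 2 or on replicates 3 and 4 called 1481 and 811 up, and 1675 and 1083 down. The calls of the days overlapped: 1529 genes were higher on both days, where independent lists would share 657, and 1265 were lower on both, where independent lists would share 511. A further 157 went from higher to lower and 122 from lower to higher, against 652 and 515 for independent lists. Across genes, which are not independent replicates, the log2 fold changes of the days correlated with Pearson r = 0.573 and Spearman rho = 0.45.

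Uninfected cells also changed between day 1 and day 5, a background of change without bacteria. Arg1 (ENSMUSG00000019987.10), the arginase of alternatively activated macrophages, went from 0.247 ± 0.120 to 57.7 ± 31.3 CPM (log2 fold change 7.82 ± 0.68, n = 4 against 4, adjusted p = 1e-06). Adm (ENSMUSG00000030790.16), the hypoxia-induced peptide adrenomedullin, rose by 4.36 ± 0.26 and P4ha2 (ENSMUSG00000018906.15), a collagen prolyl hydroxylase subunit, by 5.28 ± 0.47. Of 24 genes of glycolysis and hypoxia 21 were higher and 1 lower on both adjustments, with a median of 1.39 (camera adjusted p = 8.01e-24, adjusted p = 0.16 with an estimated correlation). Ciita, the master regulator of class II genes, rose by 3.87 ± 0.17 and H2-Eb1 by 2.51 ± 0.23, and 9 of 18 antigen-presentation genes were higher and 0 lower on both adjustments (camera adjusted p = 1.59e-07, adjusted p = 0.239 with an estimated correlation).

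Some interferon-stimulated genes rose without bacteria: 13 of 32 were higher and 0 lower, and 15 and 0 when adjusted over the list alone, with a median of 0.91 (camera adjusted p = 1.59e-07, adjusted p = 0.733 with an estimated correlation). Oas2 went from 1.60 to 6.54 CPM, against 225 CPM in exposed day 5 cells. Of 16 tested genes of alternative activation 8 were higher and 1 lower, and 9 and 2 when adjusted over the list alone (camera adjusted p = 0.000209, adjusted p = 0.0531 with an estimated correlation). Proliferation lists were lower by camera, with few single calls: 5 of 33 G1/S genes (2 adjusted over the list alone, camera adjusted p = 0.000107) and 2 of 32 G2/M genes (1 adjusted over the list alone, camera adjusted p = 9.31e-05). Neither was called with an estimated correlation (adjusted p = 0.733 for each) or by fry (adjusted p = 0.228 for each). Mki67 fell by 0.64 ± 0.17 on the log2 scale, and Card14 (ENSMUSG00000013483.15), a scaffold of NF-kB signalling, fell by 1.86 ± 0.18.

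edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment called 1852 genes higher and 1532 lower in uninfected cells at day 5 than at day 1. A fit on the 8 uninfected libraries by themselves called 3386 and 3038, fits on replicates 1 and 2 called 422 and 187, fits on replicates 3 and 4 called 386 and 195, and leaving out uninfected day 5 replicate 4 gave 1227 and 881. The count of lower genes was 1016 without uninfected day 1 replicate 1, 951 without uninfected day 1 replicate 4 and 1018 without uninfected day 5 replicate 3.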

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

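The tests of difference between the days below were planned, and none was chosen after the results were seen, apart from the choice of measures in which single libraries were compared with their group.

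Exposure effects that differed between the days are listed here because their interaction test passed the threshold, each as the log2 effect at day 5 minus that at day 1. Among the 79 tested genes named in the text 63 did so, against 35.9% of all genes tested. The naming rule takes genes with called shifts, so a high share is built in. The effect shifted most upward for H2-M2 (8.93), Lcn2 (6.19), Saa3 (5.94), Cp (5.13), Il1b (4.98), Ccl17 (4.80), Hp (4.57), Il6 (4.43), Pdgfrb (4.43), Camp (4.00), Tnip3 (3.55) and Tnf (3.45). Smaller upward shifts were those of Clec4e (2.96), Acod1 (2.82), Ccl2 (2.74), Mmp2 (2.50), Rsad2 (2.44), Slc7a11 (2.41), Mmp12 (2.30), Itgax (2.19), H2-Aa (2.05), Tnfaip3 (2.02), Gbp3 (1.97), H2-Eb1 (1.88), Slc11a2 (1.71), H2-K1 (1.68), Lck (1.66), Chac1 (1.63), Ctsb (1.60) and Casp4 (1.53), followed by B2m (1.41), Nfkbie (1.31), Nr1d1 (1.20), Isg15 (1.19), Fth1 (1.17), Card14 (1.16), Abca1 (1.16), Bcl2 (0.63), Glb1 (0.62), Tlr2 (0.59), Fas (0.52) and Atm (0.52). Downward shifts were those of Mmp8 (-4.21), Fabp1 (-3.87), Ciita (-2.04), Cdkn2a (-2.00), Lmnb1 (-1.78), Srebf1 (-1.76), Chil3 (-1.62), Adm (-1.57), Fen1 (-1.56), Aurka (-1.53), Oas2 (-1.45) and Cdkn2c (-1.41), then Cdh1 (-1.19), Socs1 (-1.19), Xbp1 (-1.04), Rtp4 (-1.03), Gclc (-0.86), Hmgb1 (-0.78), Cdkn2d (-0.75), Mki67 (-0.67) and Pparg (-0.59). Uninfected levels of Adm, Ciita, Oas2 and Rtp4 rose between the days, so their downward shifts do not show a fall in exposed cells. Ciita, Lcn2, H2-Aa and H2-Eb1 were called with opposite signs on the days: Ciita was higher at day 1 and lower at day 5, and the others the reverse. The day 5 call on H2-Eb1 was lost with no filter (adjusted p = 0.0883), in the day 5 libraries alone (0.0832), in replicates 3 and 4 alone (0.239), without the libraries of the other code series (0.279) and without any of exposed day 5 replicates 2, 3 and 4 and uninfected day 5 replicates 1 and 2 (0.0501 to 0.0976). That on H2-Aa was lost without the libraries of the other code series (0.212) and in replicates 3 and 4 alone (0.0575). Some calls on the shift were lost with 1 library fewer, at shifts of the same sign. That on Rsad2 ended without exposed day 5 replicate 2 (2.18, adjusted p = 0.0588) and with no filter (2.48, adjusted p = 0.0622). That on Tlr2 ended without exposed day 5 replicate 4 (0.48, adjusted p = 0.0553), and those on Fas, Isg15, Mki67 and Rtp4 without each of several libraries, exposed day 5 replicate 2 among them for Isg15 (0.89, adjusted p = 0.0626) and Mki67 (-0.59, adjusted p = 0.0657).

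Of the gene lists, camera with the preset correlation placed 18 apart in that change. Their median shifts were 2.80 for cytokines and chemokines, 1.62 for antimicrobial effectors, 1.58 for metalloproteinases and the plasminogen system, 1.31 for the NF-kB response, 1.10 for antigen presentation, 0.81 for SASP factors, 0.77 for type I interferon-stimulated genes, 0.72 for genes of the interferon-gamma type, 0.39 for the lysosome and 0.34 for metal handling. Downward medians were -1.56 for G2/M, -1.33 for G1/S, -1.03 for mitochondrially encoded genes, -0.77 for the DNA damage response, -0.55 for LXR and lipid handling, -0.51 for oxidative phosphorylation, -0.45 for ribosomal proteins and -0.41 for CDK inhibitors. With an estimated correlation 0 lists passed, with 4 up and 0 down at an unadjusted p under 0.05, and fry placed 8 up and 10 down. The lists for CDK inhibitors and for genes of the interferon-gamma type lost their call without single libraries, at adjusted p of 0.078 without exposed day 5 replicate 3 and of 0.0594 without exposed day 5 replicate 2.

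Single libraries stood apart from the other 3 of their group in 21 of 352 groups of 4 compared, by a gap over 0.829 of the group's range, where chance gives about 1 in 20 groups, or 18. The total pools single genes with measures of whole libraries. It therefore does not show that the latter were extreme only as often as chance gives. Exposed day 1 replicate 4, which has the smallest total, stood apart on all 3 principal components, with ratios of 0.868, 0.952 and 0.897, and in Mmp8, which it held at 9.21 CPM against 12.86 to 13.46 (0.86). Without it 1706 genes were higher and 1220 lower at day 1, against 2297 and 1800 with it, and 1706 and 1236 were called without uninfected day 1 replicate 4. Uninfected day 5 replicate 4 stood apart on the third component (0.888), in Nos2 at 0.506 CPM against 0.217 to 0.254 (0.873) and in Cdkn1a at 277 CPM against 304.8 to 310.4 (0.832), and without it 1227 genes were higher and 881 lower between uninfected days. Exposed day 1 replicate 1 had 1.13% of its counts in genes without a symbol, against 0.377% to 0.506% (0.829), and was the 1 library of its group with reads of Ccl20 (1). Uninfected day 1 replicate 1 stood apart on the first component (0.886) and in H2-M2 (0.839).

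Among exposed libraries, Cxcl10 was lowest in day 1 replicate 3, at 13.1 CPM against 19.25 to 19.3 (0.992). Cdkn2a was highest in day 5 replicate 1, at 4.52 CPM against 3.01 to 3.16 (0.902), Camp in day 5 replicate 3 (0.842) and Socs1 in day 5 replicate 4 (0.837). Among uninfected libraries at day 5, B2m was highest in replicate 3 (0.853), Ccr7 in replicate 1 (0.972) and Nr1d1 lowest in replicate 2 (0.831). At day 1, Fen1 was highest in replicate 3 (0.852), while replicate 2 held the lowest Trp53 (0.873) and the highest Xbp1 (0.952). No data lay outside the comparisons of the report.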

How the results depend on the processing

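Of the alternatives below, those for lists and overlaps with single libraries left out were chosen after the data were seen, and the others were planned. No called value of a gene named in the text changed sign under the alternatives run, while 87 values of uncalled genes did. Of 5743 values for these genes, 5433 kept their side of the threshold, 253 lost their call and 57 gained it.

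The numbers of genes called moved by over 1.5 times with the libraries used. At day 1, replicates 1 and 2 alone gave 813 higher and 406 lower genes, replicates 3 and 4 alone 568 and 156, and the libraries of that comparison alone 3650 and 3371, with 2191 and 1791 of those called in the fit of all 16. The change between days gave 1481 and 1675, then 811 and 1083, from the same subsets. Uninfected days gave 422 and 187, then 386 and 195, and 3386 and 3038 from their own libraries. Subsets hold fewer libraries by construction. The fit of all 16 shares 1 dispersion per gene among groups of unequal spread. The median standard deviation was 0.299 log2 CPM in exposed day 5 libraries and 0.113 to 0.148 in the other groups. Counts rose in fits on a comparison's own libraries where these leave exposed day 5 out, and fell at day 5 itself (8185 against 9797 called). How much of this comes from the shared dispersion was not tested. Day 5 counts stayed within 1.5 times under every alternative run.

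With single libraries left out, uninfected days gave 1227 to 1727 higher and 881 to 1407 lower genes. The lowest of both came without uninfected day 5 replicate 4, and lower counts also fell to 1016 without uninfected day 1 replicate 1, 951 without its replicate 4 and 1018 without uninfected day 5 replicate 3; the cause was not tested. Day 1 gave 1706 to 2042 higher and 1220 to 1426 lower, the lowest without exposed day 1 replicate 4, with 1706 and 1236 without uninfected day 1 replicate 4. Day 5 gave 4594 to 5043 and 4550 to 5062, and the change 2454 to 3450 and 2945 to 3920.

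The replicate number as a block gave 2216 higher and 1740 lower genes at day 1, 4810 and 4826 at day 5, 2725 and 3267 for the change and 1727 and 1434 between uninfected days. Libraries with the same number did not resemble each other across groups: the median r of 24 pairs was 0.034 (-0.452 to 0.352), with 9 over 0.1, so they were not treated as paired.

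For lists, camera with an estimated correlation called 0 up and 0 down in each comparison (unadjusted p under 0.05: 7, 6, 4 and 3 up, 0 down), and fry called 1 list down at day 1, 12 at day 5 and 1 between uninfected days, against 3, 7 and 6 by camera with the preset correlation. The 2 runs of camera ask the same question and differ in the correlation used, 0.01 against estimates of up to 0.917 (G2/M) over all 16 libraries. Fry asks a different question, and the cause of its differences from camera was not tested. With single libraries left out, the unfolded protein and metal lists gained a call at day 5 without exposed day 5 replicate 3 (adjusted p = 0.00281 and 0.011), and the former also without exposed day 5 replicate 1 (0.0489) and without uninfected day 5 replicate 3 (0.0442). The cholesterol list at day 1 lost its call with RLE size factors (adjusted p = 0.0631) and without any of exposed day 1 replicates 1, 2 and 3 and uninfected day 1 replicates 1, 3 and 4 (0.0545 to 0.0837). Camera and fry gave opposite directions for some lists that neither called, among them autophagy at day 1.

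Among single genes, the effect on Arg1 at day 5 (-1.05, adjusted p = 0.0556) was called with the replicate block (-1.17, adjusted p = 0.0305), in replicates 1 and 2 alone (-0.70, 0.0364), without the libraries of the other code series (-1.98, 0.0056), without exposed day 5 replicate 3 (-1.80, 0.00151) and without uninfected day 5 replicate 1 (-1.24, 0.0405) or 2 (-1.27, 0.0287). H2-Aa and H2-Eb1 lost their day 5 calls without the 2 libraries of the other code series (adjusted p = 0.212 and 0.279). At day 1, Aurka, Hmgb1 and Mki67 lost their calls without single libraries, exposed day 1 replicate 4 among them (adjusted p = 0.128, 0.106 and 0.0734). RLE size factors and DESeq2 moved the median of all genes by at most 0.045 (day 1: 0.027 to -0.003; change: -0.04 to 0.005) and the share of day 1 calls that were higher from 56.1% to 49.2% and 49.1%, and that for the change from 45.8% to 50.6% and 50.8%. Depth limits genes with few counts, such as Nos2 at day 1 (9 counts against 0).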

Other observations

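Receptors and defence genes outside the cytokine lists moved as well, and these results stand beside those of the report. Of 28 genes of microbial sensing 15 were higher and 2 lower at day 1, and 17 and 2 when adjusted over the list alone (camera adjusted p = 1.47e-05, adjusted p = 0.211 with an estimated correlation). The member left untested, Tlr4, is in the files but had 0 counts in every library. Whether it is missing from this line or was lost in counting was not tested. Other lists also had members with almost no counts, among them Sgsh of the lysosome list and Pycard of the cell-death list. These had at most 1 and 2 counts in any library, so Tlr4 does not stand alone. Why such counts were so low was not tested. At day 5, 16 were higher and 5 lower on both adjustments (camera adjusted p = 0.00308, adjusted p = 0.335 with an estimated correlation). Clec4e, the receptor Mincle that binds mycobacterial glycolipids, rose by 2.35 ± 0.25 and 5.30 ± 0.28 on the log2 scale, and Tlr2, a sensor of bacterial lipoproteins, by 1.29 ± 0.14 and 1.88 ± 0.14. Of 19 metal-handling genes 11 were higher and 5 lower at day 5 on both adjustments, without a camera call (adjusted p = 0.0579). The exposure effect shifted up between the days in 8 and down in 1 (camera adjusted p = 0.00486, adjusted p = 0.534 with an estimated correlation). Cp, the ferroxidase ceruloplasmin, rose by 5.48 ± 0.23, Slc11a2, an iron importer, by 2.13 ± 0.13, and Fth1, ferritin heavy chain, by 1.53 ± 0.15 to 40760 CPM. In 26 genes of the BCL2 family and cell death, 10 were higher and 2 lower at day 1 (10 and 4 adjusted over the list alone, camera adjusted p = 0.035, adjusted p = 0.385 with an estimated correlation). The counts were 12 and 7 at day 5 (13 and 7, camera adjusted p = 0.123). There Casp4, the mouse caspase-11 that senses cytosolic lipopolysaccharide, rose by 3.28 ± 0.20.

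Of all genes tested at day 5, 57% were called by edgeR, with 50.2% of those calls higher. Calls in both directions thus do not mark a list by themselves. Alveolar macrophage identity genes were called both ways at day 5: of 28, 9 were higher and 12 lower, and 9 and 13 when adjusted over the list alone (camera adjusted p = 0.31). Itgax, the integrin CD11c, rose by 2.27 ± 0.11, while Pparg, the regulator of the alveolar programme, fell by 1.05 ± 0.10 and Fabp1, a fatty-acid binding protein, by 3.82 ± 0.26. Of 16 alternative-activation genes 6 were higher and 8 lower (6 and 10 adjusted over the list alone, camera adjusted p = 0.344), with a median of -0.50 and a mean of 0.10. Chil3, a chitinase-like lectin, fell by 2.43 ± 0.21. Genes answering oxidative stress went both ways, 7 of 22 higher and 10 lower on both adjustments (camera adjusted p = 0.275): the cystine importer Slc7a11 rose by 3.30 ± 0.26, and Gclc, which makes glutathione's precursor, fell by 1.37 ± 0.06. For the unfolded protein response, 11 of 23 genes were higher and 2 lower on both adjustments (camera adjusted p = 0.0569, but 0.00281 without exposed day 5 replicate 3, 0.0489 without its replicate 1 and 0.0442 without uninfected day 5 replicate 3). Chac1 stood at 2.08 ± 0.18 and Xbp1 at -1.36 ± 0.08. Autophagy genes had 10 of 23 higher and 4 lower on both adjustments (camera adjusted p = 0.209), and genes of glycolysis and hypoxia 7 of 24 higher and 11 lower on both adjustments (camera adjusted p = 0.455). Cholesterol synthesis genes were higher at day 1 in 8 of 20 and lower in 0 (10 and 1 adjusted over the list alone, camera adjusted p = 0.0423, adjusted p = 0.602 with an estimated correlation, lost without any of 6 single libraries), and at day 5 in 8 against 5 lower (camera adjusted p = 0.692). The ribosomal protein genes that were called pointed up at day 1 and mostly down at day 5, while 19 and 15 of 30 were not called. At day 1, 11 were higher and 0 lower (12 and 0 adjusted over the list alone, camera adjusted p = 0.00393, adjusted p = 0.59 with an estimated correlation).

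Markers of other cell types served as a check on the culture. Of 12 T and NK cell genes 2 passed the filter and both were higher at day 5, Lck reaching 11.5 CPM. For B cells and for erythroid and mast cells 1 gene each was tested and 0 were called by edgeR. Of 3 epithelial genes 2 were lower at day 5, Cdh1 by -1.98 ± 0.13. Of 7 fibroblast and endothelial genes 3 were higher and 2 lower (camera adjusted p = 0.575), Pdgfrb reaching 4.48 CPM. Of 11 neutrophil genes 3 were higher and 6 lower (camera adjusted p = 0.221), Camp reaching 4.38 CPM. All 5 dendritic-cell genes were higher at day 5 (camera adjusted p = 0.0153, adjusted p = 0.137 with an estimated correlation), among them Ccr7 at 0.373 CPM. At day 1, 2 of the 5 were higher (camera adjusted p = 0.0463, adjusted p = 0.206 with an estimated correlation), a call lost without any of exposed day 1 replicates 1 and 2 and uninfected day 1 replicates 2 and 3 (0.0556 to 0.0608). Activated macrophages also express several of these genes, and no list was tested as a source of other cells.

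The tests of library code series, foreign RNA, scaling, abundant genes, CDK inhibitors and Cdkn1c were chosen after the results were seen, while those of library size, of response strength and of other splits were written down first. For foreign RNA, an earlier comparison of median shares left the question undecided and was replaced. For abundant genes, an earlier test used the median after TMM, which TMM centres whatever the cause, and was replaced as well.

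Exposed day 5 libraries varied most. Their mean score on the cytokine list was 3.17, 4.46, 3.51 and 4.42 for replicates 1 to 4, and on G2/M genes -1.78, -2.92, -2.10 and -3.02. If the library code alone made this spread, replicates 2 and 3, which carry another series, would lie side by side. They lay apart by 0.663 of the range or more. This measure was chosen after the scores were seen and cannot exclude a shift by code series on top of other differences. Depth was argued against, since thinning every library to 46154875 reads left at least 0.973 of the range. A candidate explanation is a response that had gone further in replicates 2 and 4: differences between libraries followed the exposure effect measured in the other libraries with r = 0.414 across genes in the weaker of the pairs named in advance, short of the 0.5 set for it, so strength of response and other differences between cultures cannot be told apart.

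Of 32 interferon-stimulated genes, 13 were higher in uninfected cells at day 5 than at day 1 and 19 were not called (list adjusted p = 0.733 with an estimated correlation). Reads or RNA from exposed day 5 cultures would carry every abundant induced transcript at 1 share, but the 13 called genes needed a median share of 1.17% (0.267% to 7.9%), while of 24 induced genes of at least 100 CPM the 5 lowest, among them H2-M2, stayed at or under 0.224%, and the others lay above it. With RLE size factors 13 of the 13 stayed called. These moved the median of all genes by only -0.019, so the choice between the 2 scalings does not make the calls. A larger error of scaling was not tested. Time in culture, medium use and density remain open and were not tested.

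Proliferation genes were lower in exposed cells at day 5, when 1 of 7 CDK inhibitors was called higher. If abundant induced transcripts had merely taken up the counts, other genes would have fallen alike, yet with libraries scaled to total counts only, without TMM, the median log2 ratio of the 17131 tested genes with counts in both day 5 groups was -0.066, against -1.88 and -2.12 for G1/S and G2/M genes. A 2-fold or larger induction of CDK inhibitors at the mRNA level was argued against for the 6 with at least 5 CPM in an exposed group, whose highest upper 95% limit was 0.25 (Cdkn2b). The called one, Cdkn1c (0.98 ± 0.28), had a mean of 0.889 CPM in exposed cells, too low to decide, and stays open. The limit of 0.25 is of group means and rests on a dispersion shared by all groups. It does not measure the wider spread among exposed day 5 libraries. Replicates 2 and 4, with the lower G2/M scores, held Cdkn1a at 371 and 327 CPM, above the uninfected libraries. A small rise in some cultures therefore stays open. Regulation of these inhibitors as proteins, loss of dividing cells and slower growth from nutrient use may each contribute and were not tested.

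Other splits of the libraries excluded a random grouping in each comparison of 2 groups, but did not test the numbers of genes called. In fits of 8 libraries the real labels called 7021 genes at day 1, 8185 at day 5 and 6424 between uninfected days, and each of the other splits called 0, so 1 of the 35 splits gave as many. That is the lowest share that 35 splits can give. Every other split mixes the labels, which widens the spread within its groups and lowers its calls. For the change between days 1 of 100 relabelings gave as many as the real 6173, with 5800 as the highest other. The 2 drawn relabelings that kept the exposed day 5 libraries together called 5702 and 5800, and the others called at most 12. A random grouping of the libraries of both days together was thereby excluded. For the change, a random grouping of the day 1 libraries alone was not, since only those 2 relabelings bear on it. The number of genes whose effect differs between days was not tested by these relabelings, since the day 5 group alone carries most such calls. Calls shared in direction by both days numbered 2794 with the real labels and 0 in each of the others, which likewise speaks to the grouping and not to the amount shared. Chance was not excluded for the number of lists called by camera with the preset correlation, and these splits cannot settle it. Many keep 3 libraries of 1 label together and so hold part of the real difference. At day 1 the real labels called 14, which 6 of 35 splits reached (highest other 17). At day 5 they called 18, which 5 of 35 reached (19), between uninfected days 17, which 2 of 35 reached (17), and for the change 18, which 22 of 100 reached (21). Among the drawn relabelings, those with 2 libraries of each label in every group called at most 10 lists. List calls of that kind therefore rest on the genes called within each list, and the number of lists is not evidence by itself.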
